A study of Mus musculus with 52 samples.

How the data were processed

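Of 52 samples in the series, 30 were analysed. CUT&Tag libraries and ATAC-seq of asynchronous cells fixed with formaldehyde or ethanol were not analysed here. Groups were read from the sample labels alone. Per the labels, sorted ATAC-seq cells were fixed with 1% formaldehyde and sorted SLAM-seq cells with ethanol. Treated RNA-seq cells were given EdU, ethanol-fixed and stained, while asynchronous RNA-seq cells were fresh and without EdU. Cells of the synchronised ATAC-seq were all fresh, with EdU given to the drug-treated ones only. The labels do not say whether replicates came from separate cultures.

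The values used were counts as deposited by the authors. Per the file headers, SLAM-seq read counts and T>C read counts per 3′ UTR came from slamdunk 0.3.4, and the tables include multimapping reads (18.3% to 21.4% of reads). Per the submitters' processing notes the genome build was mm10, and the tools were CASAVA 1.8, Bowtie2, Picard, MACS2, deepTools, DESeq2, cutadapt 1.15, STAR, SAMtools and HTSeq, named without the step or assay each was used for. Per the names of the deposited files, RNA-seq counts came from HTSeq and ATAC-seq counts were taken over MACS2 peaks. The notes do not give the strand setting of HTSeq, so antisense partners cannot be separated, nor whether peaks were called per library or pooled. The score of each element-gene pair was deposited by the authors as the output of an activity-by-contact model, in which activity times contact is divided by its sum over the elements of a gene. A deposited table of DESeq2-normalised counts was not used here, since each column equals the raw counts divided by 1 constant.

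SLAM-seq counts were summed per gene over 32947 3′ UTR rows; 277 rows named no gene and held 0.397% to 0.587% of reads, leaving 20690 genes. In RNA-seq, the 5 summary lines of HTSeq, 8.50% to 13.0% of counts, were set apart from 53656 genes. Mitochondrial peaks were left out of ATAC-seq library sizes and tests, leaving 101735 nuclear peaks in sorted cells (median width 143 bp, median count per peak 7 to 11) and 166755 in synchronised cells (364 bp, 25 to 61); they held 1.39% to 6.57% of peak counts in synchronised libraries. A gene's promoter peak was the tested peak with the highest count within 1 kb of its start, with gene starts from RefSeq for GRCm38.p6. Distal elements were non-promoter elements with a score of at least 0.02 (39336 pairs of 13827986).

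Differential tests used edgeR quasi-likelihood fits with TMM factors, filterByExpr by group and robust dispersion, with all libraries of a table in 1 fit and group as the only factor. Genes or peaks were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The test of new RNA is relative to other labelled transcripts, because T>C reads were scaled among themselves. Factors ranged from 0.966 to 1.04 for new RNA, 0.885 to 1.14 for RNA-seq and 0.917 to 1.10 for synchronised ATAC-seq. The common biological coefficient of variation was 0.771 for new RNA, 0.427 for all SLAM-seq reads, 0.209 for sorted ATAC-seq, 0.109 for synchronised ATAC-seq and 0.0613 for RNA-seq. SE values come from the edgeR fit. Where a group had 0 counts no fitted fold is given; a lower bound was set with a floor of 3 counts over that group.

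The 17 gene lists, from 15 to 79 genes, were written from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with fewer than 5 measured genes were not tested. Some lists hold markers of other cell types, and RNA of pooled cells cannot tell a change within cells from a change in their mix. Each list was tested with camera of limma on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of a comparison, with a run at an estimated correlation beside it. A rotation test, fry, was planned and run as well. Passing as a set refers to camera unless fry is named. In ATAC-seq the lists were read through promoter peaks. Genes were named by a fixed rule: the up to 6 largest rises and 6 largest falls among called genes with non-overlapping replicates and a mean of at least 20 CPM in the higher group (50 CPM for new RNA), leaving out predicted genes and marked pseudogenes, the up to 4 members of each list with the smallest adjusted p, and 10 genes always followed (Ccne1, Ccnb1, Cdk1, Plk1, Mcm2, Ccnd1, Pou5f1, Nanog, Cdkn1a and Myc). Not every gene the rule selects is printed. Results for some of them are not reported here. For ATAC-seq it gave the 4 largest rises and falls and the promoters of the 10 genes. Labelled shares were compared with exact permutation tests and correlations with permutation tests of 100000 resamples, all two-sided.

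The same code was run on simulated counts with log2 changes set in 200 features. Counts were drawn feature by feature, independently, from the means, library sizes and dispersions of the data. For ATAC-seq a random part of the peaks was used, 28947 tested for sorted and 58501 for synchronised cells. The 200 changed features are far fewer than the genes called in RNA-seq, so recovery and false calls there may differ. Changed features were taken only from those with higher expected counts, so recovery of features with low counts was not measured. Of features changed by 1, 6% were recovered in new RNA, 34% in all SLAM-seq reads, 12% in sorted ATAC-seq, 86% in RNA-seq and 66% in synchronised ATAC-seq; at 3 these shares were 64%, 76%, 98%, 100% and 96%. False calls were 1 of 49, 4 of 97, 8 of 104, 14 of 182 and 12 of 143. In simulated RNA-seq counts, camera called a list of 40 genes shifted by 0.5 and did not call an unshifted one. Genes were drawn independently there too, so correlation between genes was not part of the test. Alternatives were DESeq2, median-ratio factors, total counts only, no low count filter, only the 2 groups compared, the replicate number as a block, leaving out each library, scaling T>C reads by all reads, conversions per T position, a promoter window of 500 bp, a score of at least 0.05 and, added later, mitochondrial peaks kept. Scaling T>C reads by all reads shifted the median of all genes by 0.24 in S against G1 and 0.20 in G2M against G1. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.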

Results

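E14 mouse embryonic stem cells, a male line grown in serum with the cytokine LIF, were separated by cell cycle phase in 2 ways. In sorted cells, a 10 min pulse of 20 nM EdU, a thymidine analogue that marks replicating DNA, was combined with DAPI staining of DNA content to collect G1, S and G2M cells from a fixed, unperturbed culture. In synchronised cells, nocodazole (microtubule poison, mitotic arrest), double thymidine (arrest of replication) or RO-3306 (CDK1 inhibitor, arrest before mitosis, CDK1i below) was set against asynchronous cells. Sorted cells had ATAC-seq, which measures open chromatin, with 2 libraries per phase, and SLAM-seq, in which RNA made during a 2 h pulse of 4-thiouridine carries T>C conversions, with 3 G1, 3 S and 2 G2M libraries. Synchronised and asynchronous cells had RNA-seq and ATAC-seq with 2 libraries per group. SLAM-seq libraries held 3487939 to 6031541 reads in 3′ UTRs, of which 320557 to 583568 carried T>C conversions. RNA-seq libraries held 13158766 to 37207217 reads in genes. ATAC-seq libraries held 1102935 to 2069821 reads in nuclear peaks from sorted cells and 11040528 to 23942094 from synchronised cells. Values after ± are the SE for log2 fold changes and the SD over libraries for levels in CPM, counts scaled to the library total. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

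Labelling asked whether the share of new RNA differs between phases. The share is relative to all reads of a library, so it does not give the amount of RNA made per cell. Because the 2 h pulse came before sorting, labelled RNA can include RNA made in the phase before. T>C reads made up 8.38% ± 0.717 (SD, n = 3) of reads in G1, 9.82% ± 0.645 (n = 3) in S and 9.89% ± 0.298 (n = 2) in G2M. All 3 S libraries (10.5%, 9.79% and 9.19%) and both G2M libraries (10.1% and 9.68%) lay above all 3 G1 libraries (8.86%, 7.56% and 8.73%). The mean of S was 1.44 percentage points above G1 (two-sided exact permutation test, p = 0.10) and that of G2M 1.50 points above G1 (exact p = 0.10), where 0.10 is the smallest p that these group sizes allow. G2M and S differed by 0.0668 points, less than the spread between replicates (exact p = 0.90). The 95% Wilson interval of a single library was narrow, 8.84% to 8.89% for G1 replicate 1, but covers counting error only, since PCR reads are not independent molecules. The share of genes gave the same order: the median over 4312 genes was 8.44% in G1, 10.4% in S and 10.5% in G2M. Conversions per T position did not: 0.613% in G1, 0.788% in S and 0.737% in G2M put G2M below S (exact p = 0.30).

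**Figure D1:**
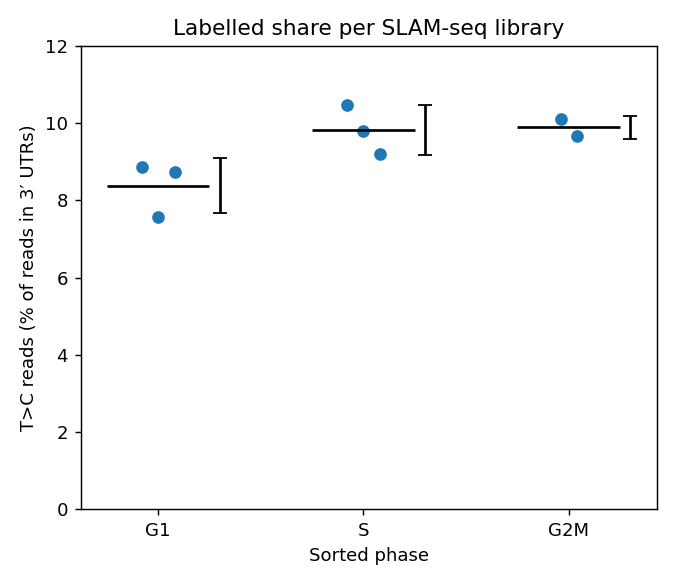
Percent of 3′ UTR reads with T>C conversions (y axis) in each SLAM-seq library of sorted G1, S and G2M cells (points); long lines are means and the brackets beside them ± 1 SD. Every S and G2M library lies above the 3 G1 libraries, whose mean is 8.38%.

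New RNA was then compared gene by gene. Mitotic genes carried more T>C reads in G2M than in the other phases as a group, and replication genes fewer in G2M and S than in G1 relative to other labelled RNA, while single genes hardly ever passed the test. Pitpnb, a phosphatidylinositol transfer protein on chromosome 5, was the only gene of 7933 tested that edgeR called: new RNA rose from G1 to S by 4.22 ± 0.62 on the log2 scale (278 ± 174 against 14.4 ± 5.56 CPM, adjusted p = 0.0219). Of the 62 measured genes of the G2/M and mitosis list, 0 passed over all genes in G2M against S and 1 rose adjusted over the list alone, yet the list as a set rose with a median log2 change of 0.76 (camera, adjusted p = 8.12e-08 and adjusted p = 0.0488 with an estimated correlation). Against G1 the same list rose in G2M by a median of 0.82, with 0 genes called and 3 rising adjusted over the list alone (adjusted p = 1.55e-06 and adjusted p = 0.0506 with an estimated correlation). Ccnb1, the mitotic cyclin, had a change of 1.15 ± 0.25 from S to G2M, and Top2a, the DNA topoisomerase that untangles chromosomes, of 1.43 ± 0.30 from G1 to G2M; neither passed. The G1/S and DNA replication list (54 genes) fell in G2M against G1 with a median of -0.37, with 0 genes called over all genes or adjusted over the list alone (adjusted p = 0.000427 and adjusted p = 0.0506 with an estimated correlation). It also fell in S against G1 with a median of -0.31, 0 genes called and 2 falling adjusted over the list alone (adjusted p = 0.0463 and adjusted p = 0.201 with an estimated correlation); E2f2, a transcription factor of S-phase entry, had -1.98 ± 0.52 without passing. p53 targets fell in S against G1 (median -0.46, 26 genes, 0 called, 1 adjusted over the list alone, adjusted p = 0.0463 and adjusted p = 0.201 with an estimated correlation). In G2M against G1 they fell too (median -0.20, 0 called, 0 adjusted over the list alone, adjusted p = 0.0433 and adjusted p = 0.140 with an estimated correlation), as did immediate early genes (median -0.24, 23 genes, adjusted p = 0.00921 and adjusted p = 0.0847 with an estimated correlation) and lineage markers (median -0.40, 16 genes, adjusted p = 0.0433 and adjusted p = 0.147 with an estimated correlation), both with 0 genes called and 0 adjusted over the list alone. The rotation test fry passed the G2/M list in both comparisons and none of the falls. All these falls are relative to other labelled RNA: scaling of all reads in place of T>C reads shifted the median of all genes by 0.24 in S against G1 and 0.20 in G2M against G1. With it, medians in S against G1 were -0.054 for the G1/S list (adjusted p = 0.127) and -0.19 for p53 targets (adjusted p = 0.0808), neither passing. In G2M against G1 they were -0.20 for the G1/S list (adjusted p = 0.00110), -0.046 for immediate early genes (adjusted p = 0.0241), -0.0030 for p53 targets and -0.18 for lineage markers (both with an adjusted p = 0.0563, not passing). Sox2, a core pluripotency factor, had 0.87 ± 0.18 in S against G1 (adjusted p = 0.174), and Tet1, a 5-methylcytosine oxidase, 0.85 ± 0.20. edgeR called 0 genes in G2M against S (149 at an unadjusted p under 0.05; 1 by DESeq2) and 0 in G2M against G1 (412 at an unadjusted p under 0.05; 4 by DESeq2); in S against G1, DESeq2 called 28 higher and 8 lower. In S against G1, edgeR called 0 genes with only the 2 groups in the fit. It called more than 1 with no low count filter or with scaling by all reads. Counts this small also turned on single libraries. In S against G1, 0 genes were called without G1 replicate 1, G1 replicate 3, S replicate 1 or S replicate 3 and 2 without G1 replicate 2; in G2M against G1, 2 were called without G1 replicate 2 and 1 without G2M replicate 2.

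All SLAM-seq reads, labelled or not, gave the standing RNA level of each phase. In S against G1 the pluripotency factor Sox2 rose by 0.94 ± 0.13 (2992 ± 418 against 1557 ± 56.0 CPM, n = 3 per phase, adjusted p = 0.000269). The transcription factor Klf5 (0.80) and the oxidase Tet1 (0.81) rose with it. Of 41 measured genes of naive and core pluripotency, 6 rose, 1 fell and 34 did not pass (10 and 3 adjusted over the list alone), and the list as a set did not pass (median 0.094, adjusted p = 0.126). Pou5f1 (-0.24) and Nanog (0.080) were not called. Among 66 G2/M genes 1 rose and 3 fell (3 and 5 adjusted over the list alone). Top2a rose by 0.98 ± 0.16, while the mitotic kinase Plk1 (-1.15 ± 0.24), the spindle assembly factor Tpx2 (-0.99) and the anaphase activator Cdc20 (-1.03) fell. Cdkn1a, which encodes p21 and is a p53 target, fell too (-0.95 ± 0.19). Among the 20 D-cyclin and early G1 genes it fell together with the phosphatase Cdc25a (-0.77), 0 rose (0 and 2 adjusted over the list alone), and the list's median (0.15) and its test (down, adjusted p = 0.994) differed in sign. In the G1/S list E2f2 (-0.85) was the only called gene of 55 (1 up and 2 down adjusted over the list alone), with Mcm2, a replication helicase subunit, at -0.24. As a set the G1/S list did not pass (median -0.073, camera, adjusted p = 0.999). Immediate early genes split, 2 up and 1 down with the same counts adjusted over the list alone: the Ras pathway inhibitors Spred2 (1.25) and Spry2 (0.58) rose and the AP-1 member Jund (-0.65) fell. The ribosomal protein mRNAs Rpl29 (-0.71), Rpl27a (-0.55) and Rps16 (-0.51) fell and Rpsa (0.47) rose, of 76 measured (2 up and 5 down adjusted over the list alone).

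Large rises from G1 to S were in the zinc finger genes Zfp995 (2.18 ± 0.44) and Zfp433 (1.92), Fam167a (1.94 ± 0.25, 231 ± 31.7 against 60.6 ± 22.6 CPM), Appl2 (1.82) and Dnajc1 (1.79). The largest falls were in the ligand ephrin B1, Efnb1 (-2.58 ± 0.51), the Polycomb subunit Phc2 (-2.05), Oser1 (-2.02), the Wnt inhibitor Nkd2 (-1.94), the keratin Krt8 (-1.91) and Ripor1 (-1.87). As sets, 3 lists were lower in S: heat shock (median -0.26, 0 called, 1 up and 4 down adjusted over the list alone, adjusted p = 0.0310), the stress response list (median -0.26, 1 up, 1 up and 2 down adjusted over the list alone, adjusted p = 0.0422) and markers of fibroblasts or feeder cells (median -1.10, 11 genes, 0 called, 1 down adjusted over the list alone, adjusted p = 0.0367). Each had an adjusted p = 0.159 with an estimated correlation. Atf4, the transcription factor at the centre of the stress response, rose by 0.69, against its list. The heat shock gene Hspa4l was at 0 counts in S and at least 18.5-fold lower there against a floor of 3 counts over the group, without passing the test. Histones (9 genes, among them H1f0 and H2az1, which are not tied to replication), lineage and primitive endoderm markers, cholesterol synthesis and glycolysis did not pass as sets, with adjusted p from 0.126 to 0.595. In all, edgeR called 217 genes higher and 68 lower of 12066 in S against G1, with 4sU-treated, ethanol-fixed cells in every group. With scaling by total counts alone the split was 136 higher and 95 lower, 58.9% in place of 76.1% higher. DESeq2 and a fit with no low count filter called more genes, and a fit of only the 2 groups fewer. The 285 calls became 159 without G1 replicate 1, 165 without G1 replicate 2, 82 without S replicate 1 and 154 without S replicate 3.

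G2M cells had more RNA of mitotic genes than either other phase. Of 66 G2/M genes, 7 rose and 0 fell against S (23 and 0 adjusted over the list alone), with a median of 0.53 (camera, adjusted p = 4.23e-16 and adjusted p = 0.00172 with an estimated correlation). Against G1, 6 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.44 (adjusted p = 4.95e-13 and adjusted p = 0.00290 with an estimated correlation). Top2a rose by 2.13 ± 0.18 from G1 to G2M (744 ± 93.0 against 171 ± 6.30 CPM, adjusted p = 1.26e-07), and its start lies on chromosome 11 at 99024189 in mm10. Ccnb1 rose by 1.12 ± 0.16 against G1 and 1.03 ± 0.16 against S, and the ubiquitin-conjugating enzyme of mitotic exit, Ube2c, by 1.37 ± 0.16 and 1.17 ± 0.16. Plk1 rose by 1.53 ± 0.26 against S and had 0.39 against G1 (adjusted p = 0.823). Against S the spindle protein Nusap1 (2.01 ± 0.37), the alpha tubulin Tuba1c (1.59 ± 0.17, 1066 ± 94.9 against 353 ± 79.4 CPM), Tpx2 (1.21) and Jpt1 (1.26) rose. Against G1 the midzone protein Prc1 (1.86), the spindle protein Fam83d (1.88) and the importin Kpna2 (1.84) rose. Fzr1, an activator of the anaphase-promoting complex from the early G1 list, rose by 1.17 against S and 1.49 against G1. The replication clamp Pcna fell from S to G2M (-0.84 ± 0.16, 297 ± 11.8 against 532 ± 41.8 CPM) and was the only called gene of 55 in the G1/S list (1 adjusted over the list alone), which fell as a set (median -0.18, adjusted p = 0.00839 and adjusted p = 0.0743 with an estimated correlation). Klf5 (-0.66) fell against S, and the kinase Pim2 (-1.57) against G1. The exonuclease gene Isg20 was the largest fall in both comparisons (-2.23 ± 0.40 against S, -3.93 ± 0.42 against G1, 4.34 ± 1.22 against 66.4 ± 7.19 CPM in the latter).

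Other lists moved as sets in G2M with 0 genes called. Against S, the stress response list rose (median 0.14, 1 gene adjusted over the list alone, adjusted p = 0.0390 and adjusted p = 0.145 with an estimated correlation). Against G1, the G1/S list had a median of -0.18 (adjusted p = 0.00582 and adjusted p = 0.0753 with an estimated correlation) and 0 genes adjusted over the list alone. Lineage markers fell with a median of -0.50, or -0.43 with genes at 0 counts at their bound (3 down adjusted over the list alone, adjusted p = 0.000724 and adjusted p = 0.0910 with an estimated correlation). Primitive endoderm markers fell with a median of -0.78, or -0.51 at the bound (0 adjusted over the list alone, adjusted p = 0.00968 and adjusted p = 0.0910 with an estimated correlation). Histones (median -1.36, 9 genes), immediate early genes (-0.17), p53 targets (-0.23) and fibroblast markers (-0.96) fell too, each with an adjusted p = 0.0281 and 0 genes adjusted over the list alone; with an estimated correlation the adjusted p = 0.116 for immediate early genes and 0.0986 for the other lists. Only 9 of the 79 histone genes listed were measured. In G2M against G1, H2bc4 (0.166 against 5.98 CPM), Hist1h2ao (2.77 against 7.12 CPM) and H1f0 (49.9 against 68.2 CPM) were all lower, without passing. Levels of H2bc4 and Hist1h2ao were low in both phases. Naive pluripotency genes rose (median 0.20, 1 adjusted over the list alone, adjusted p = 0.0451 and adjusted p = 0.0986 with an estimated correlation). Foxq1, of the primitive endoderm list, was at 0 counts in G2M and at least 17.1-fold lower than in G1, where its 3 libraries differed (0.959, 7.75 and 4.43 CPM). It did not pass the test. In the same list Dab2 (67.1, 24.7 and 6.52 CPM) and Cubn (0, 5.46 and 13.6 CPM) also varied between the G1 libraries, and Fst (34.5, 58.7 and 44.3 CPM) less so. For the lineage, primitive endoderm and fibroblast lists, these data cannot tell a change within cells from a change in the mix of cells. edgeR called 13 higher and 5 lower against S and 18 higher and 4 lower against G1. DESeq2 gave 25 higher and 48 lower against S, 34.2% in place of 72.2% higher. Against G1, DESeq2 and a fit with no low count filter called more genes, and a fit of only the 2 groups fewer. The 18 calls against S became 7 without G2M replicate 1 and 3 without G2M replicate 2, and the 22 against G1 became 10 without G1 replicate 1, 14 without G1 replicate 2, 8 without G2M replicate 1 and 5 without G2M replicate 2.

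**Figure D2:**
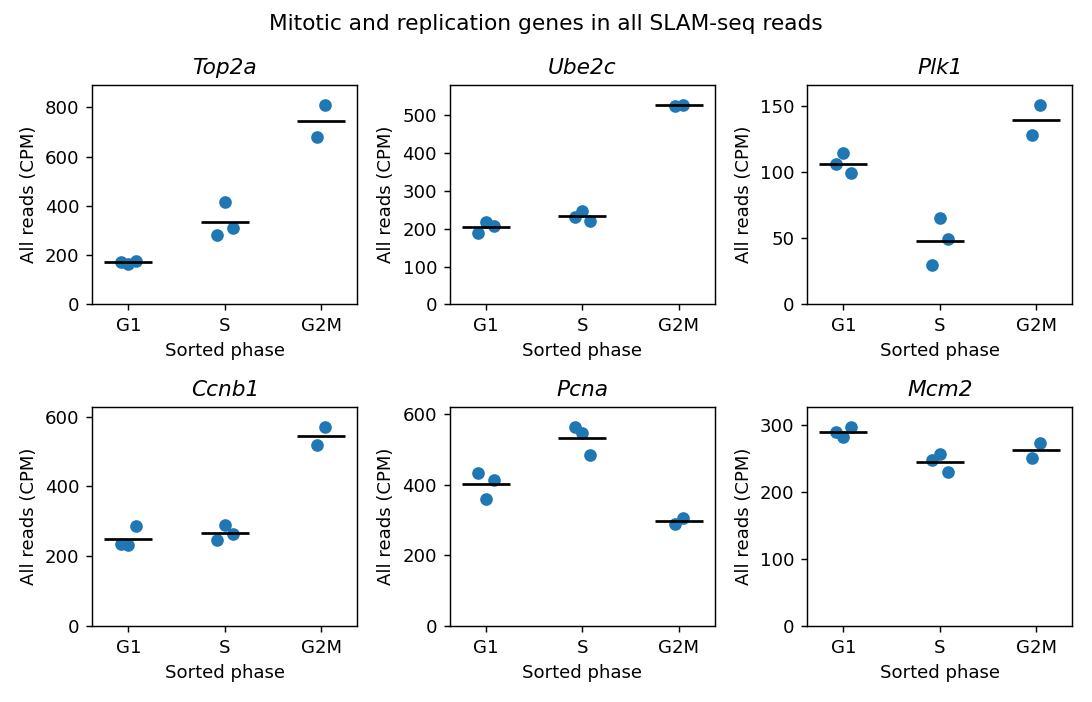
Level in all SLAM-seq reads (CPM, y axis from 0) of 5 named cell cycle genes and the replication clamp Pcna in sorted G1, S and G2M libraries (points), with group means as lines. Top2a rose from a mean of 171 CPM in G1 to 744 CPM in G2M, and Pcna was highest in S.

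Sorted ATAC-seq asked whether accessibility changes through the cycle. In S-phase cells, peaks at gene starts had lower counts than in G1 or G2M. Of 56282 peaks tested, 1005 were higher and 3198 lower in S than in G1; 39.2% of the lower peaks lay within 1 kb of a gene start, against 15.1% of the higher ones and 17.9% of all tested. The median log2 change was -0.37 within 1 kb of a gene start and 0.14 over 10 kb from any. A peak on chromosome 8 from 122567776 to 122567971 (mm10), 142 bp from the start of Cdt1, which licenses replication origins in G1, was at 0 counts in both S libraries: at least 9.86-fold lower than in G1 (edgeR, adjusted p = 9.11e-05) and at least 9.16-fold lower than in G2M (adjusted p = 0.000112). Peaks in the phospholipase gene Pla2g2e (chromosome 4, 138882209 to 138882382, at least 11.2-fold) and the membrane skeleton gene Epb41 (chromosome 4, 132025120 to 132025277, at least 10.9-fold) were lower than in G1 too. The largest rise was an intergenic peak on chromosome 2 (116329163 to 116329403, 4.28 ± 0.84). Whole 1 Mb regions had many lower peaks, a grouping added after the data were seen. On chromosome 2 from 155000001 to 156000000, 26 of 35 peaks fell, with a median of -2.00, and on chromosome 4 from 126000001 to 127000000 16 of 24 fell. DESeq2 called 103 higher and 1252 lower, 7.60% in place of 23.9% higher, and shifted the median of all peaks by -0.17, more than the distance of the distal median from 0. The 4203 calls became 2177 without G1 replicate 1, 2282 without S replicate 1 and 2358 without S replicate 2.

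From S to G2M the gene starts moved the other way. edgeR called 1821 peaks higher and 266 lower, and 57.2% of the higher peaks, 1042 in number, lay within 1 kb of a gene start. Peaks in Vwa1 (chromosome 4, 155769896 to 155770014, at least 10.9-fold) and near Ppdpf (chromosome 2, 181187891 to 181187993, at least 9.16-fold) were higher in G2M. The promoter of Ccnd1, which encodes cyclin D1, rose by 1.41 ± 0.43 (chromosome 7, 144939726 to 144939927, adjusted p = 0.0439), and a peak in Oma1, a mitochondrial protease gene, fell (-3.66 ± 1.04; chromosome 4, 103353903 to 103354006). On chromosome 11 from 120000001 to 121000000, 41 of 58 peaks rose, with a median of 1.93. G2M and G1 differed less at gene starts, with a median of -0.0084 within 1 kb, while 430 peaks were higher and 1105 lower. The lower peaks gathered on chromosome 4, where 79 of 139 fell from 146000001 to 147000000 (median -1.42) and 104 of 236 in the next Mb, and on chromosome 2, where 25 of 41 fell from 177000001 to 178000000 (median -1.49). A peak in Efl1 (chromosome 7, 82771288 to 82771865) rose by 3.22 ± 0.32, and a peak in the amino acid transporter gene Slc38a4 (chromosome 15, 97028162 to 97028313) fell (-3.88 ± 0.83). Camera passed no list of gene promoters in these 3 comparisons, while the rotation test fry, which does not set a list against other promoters, passed 10 of 13 in S against G1 (all down), 11 in G2M against S (all up) and 0 in G2M against G1. With camera the G1/S list had medians of -0.40 in S against G1 (1 up, 12 down, adjusted p = 0.782) and 0.58 in G2M against S (11 up, 0 down, adjusted p = 0.343). Against G1, DESeq2 gave 56 higher and 297 lower, 15.9% in place of 28.0% higher. The 2087 calls against S became 1115 without G2M replicate 1, 1249 without G2M replicate 2, 1331 without S replicate 1 and 1324 without S replicate 2, and the 1535 against G1 became 663 without G1 replicate 1, 934 without G1 replicate 2, 414 without G2M replicate 1 and 294 without G2M replicate 2.

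**Figure D3:**
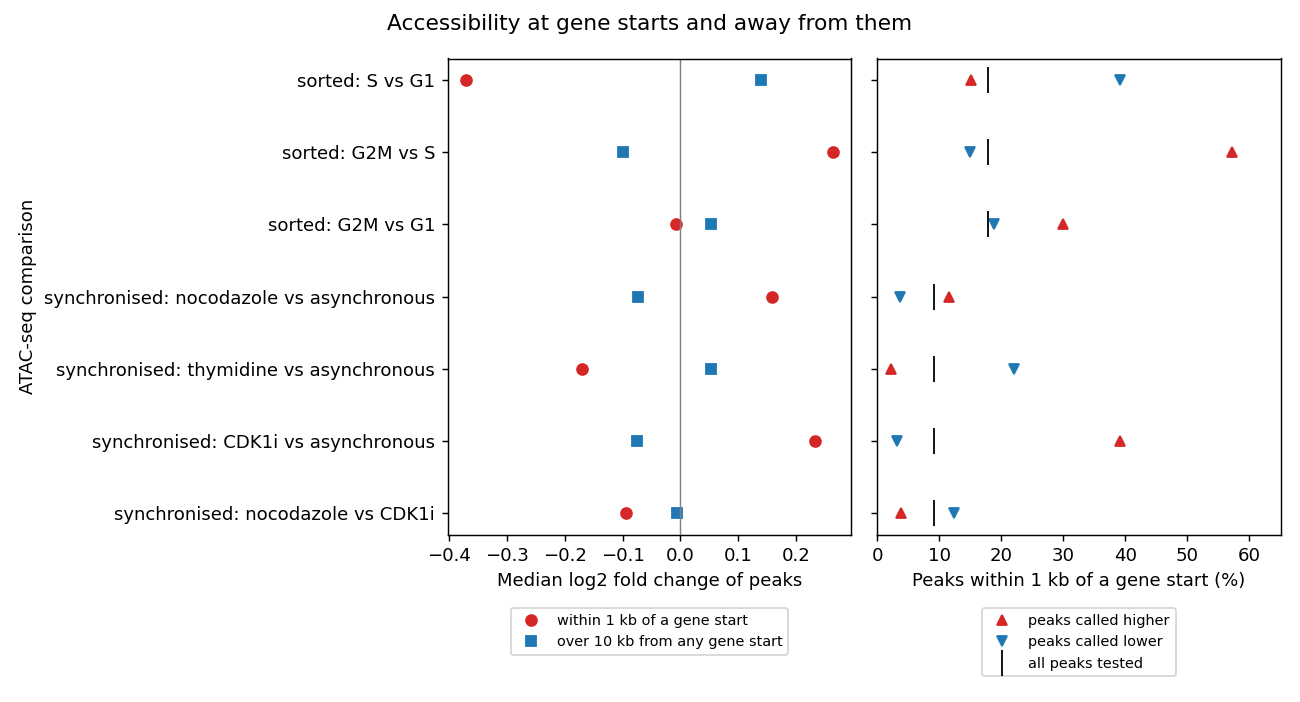
Left, median log2 fold change of peaks within 1 kb of a gene start (circles) and over 10 kb from any (squares) in each ATAC-seq comparison; right, the percent of peaks called higher (up triangles), called lower (down triangles) and of all tested peaks (bars) that lie within 1 kb of a gene start. In S against G1, gene starts have a median of -0.37 and hold 39.2% of the lower peaks; scaling by total counts alone shifts the median of all peaks by -0.15 for nocodazole and -0.16 for CDK1i against asynchronous cells.

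Whether accessibility and new RNA changed together was tested across genes with Spearman's rho, in a family of 6 relations fixed in advance, with 100000 resamples; genes are not independent replicates. From G1 to S, rho was 0.0712 for promoter peaks over 5206 genes and 0.0883 for distal elements linked to genes by the deposited enhancer-gene scores over 3853 genes. For both the permutation p = 1e-05, the smallest the resamples can give, and the adjusted p = 3e-05. From S to G2M, rho was 0.0303 for promoters (permutation p = 0.0286, adjusted p = 0.0573) and -0.0141 for distal elements (permutation p = 0.384, adjusted p = 0.384). From G1 to G2M, rho was 0.0170 for promoters (permutation p = 0.221, adjusted p = 0.265) and 0.0334 for distal elements (permutation p = 0.0384, adjusted p = 0.0576).

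Nocodazole, used to hold cells in mitosis, was compared with asynchronous cells by RNA-seq. p53 targets rose, replication and most mitotic genes fell, pluripotency genes fell and markers of fibroblasts rose. Of 34 measured p53 targets 26 rose, 1 fell and 7 did not pass (26 and 1 adjusted over the list alone), with a median of 0.89 (camera, adjusted p = 1.48e-06 and adjusted p = 0.158 with an estimated correlation). Mdm2, the ubiquitin ligase that degrades p53, rose by 2.34 ± 0.079, Plk2 by 2.39, the peptide transporter Tap1 by 3.77 and Perp by 2.47. Cdkn1a rose by 1.71 ± 0.074 (197 ± 9.16 against 60.2 ± 1.29 CPM, n = 2 per group, adjusted p = 8.24e-14). Of 63 G2/M genes 9 rose and 42 fell (9 and 42 adjusted over the list alone; median -0.51, adjusted p = 1.48e-06 and adjusted p = 0.156 with an estimated correlation). Among them Top2a (-1.96), the spindle motor Kif11 (-1.73), Cenpf (-1.71), Cdk1 (-1.28) and Ccnb1 (-1.14) fell. In sorted G2M cells Top2a (2.13) and Ccnb1 (1.12) were higher than in sorted G1 cells, a baseline unlike fresh asynchronous cells. With unlike baselines, these RNA levels do not tell whether cells were arrested. The G1/S list had 6 higher and 31 lower of 55 (6 and 31 adjusted over the list alone; median -0.20, adjusted p = 0.000720 and adjusted p = 0.198 with an estimated correlation). The DNA polymerase subunit Pola1 (-1.57), the chromatin remodeller Hells (-1.53) and Mcm2 (-0.89) fell, and Ccne1, cyclin E1, rose (0.31). Histone genes rose, 11 of 14 (11 adjusted over the list alone; median 1.68, adjusted p = 0.00569 and adjusted p = 0.198 with an estimated correlation). The linker histone Hist1h1c (2.78) was one of them, and near-identical histone copies make single genes uncertain. Of the 79 histone genes listed only these 14 were measured. Levels were low, with Hist1h2bc at 44.3 against 14.5 CPM and Hist1h1d at 3.35 against 0.675 CPM. The rise therefore does not stand for histone genes as a whole.

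Pluripotency genes fell under nocodazole, with 28 lower and 8 higher of 42 (29 and 8 adjusted over the list alone; median -0.56, adjusted p = 0.000195 and adjusted p = 0.0749 with an estimated correlation). Tbx3 (-3.20), Dnmt3l (-2.23), Fgf4 (-1.38) and Nanog (-1.29) fell, Id2, an inhibitor of bHLH factors, rose (2.48), and Pou5f1 was not called (-0.13). 2-cell-like genes, which mark a rare state with totipotent features, fell in all 12 measured (12 adjusted over the list alone; median -4.30, -4.17 with genes at 0 at their bound; adjusted p = 3.32e-05 and adjusted p = 0.0749 with an estimated correlation). Zscan4d fell (-5.02) and Zscan4e was at least 24.4-fold lower, though copies of this family share reads. Fibroblast markers rose in 12 of 16 genes and fell in 1 (13 and 1 adjusted over the list alone; median 2.14, 1.67 with bounds; adjusted p = 0.00510 and adjusted p = 0.226 with an estimated correlation). Smooth muscle actin Acta2 (5.68 ± 0.40, 9.01 ± 0.457 against 0.169 ± 0.00260 CPM) and collagen Col1a1 (2.65) rose. Keratins Krt18 (3.18) and Krt8 (1.97), the trophectoderm factor Tfap2c (2.40) and the neural factor Pax6 (2.82) rose in the lineage list, 19 up and 8 down of 39, which did not pass as a set (adjusted p = 0.152). All 9 mitochondrially encoded genes rose (9 adjusted over the list alone; median 0.90, adjusted p = 0.00192 and adjusted p = 0.251 with an estimated correlation), and mitochondrial reads made up 4.04% and 4.45% of counts against 2.09% and 2.23% in asynchronous libraries. Ribosomal proteins rose in 55 of 76 (55 up and 2 down adjusted over the list alone; median 0.31, adjusted p = 0.00398 and adjusted p = 0.666 with an estimated correlation). Glycolysis and hypoxia genes fell, 16 against 6 up (16 and 6 adjusted over the list alone; median -0.32, adjusted p = 0.0171 and adjusted p = 0.565 with an estimated correlation), with hexokinase Hk2 (-1.27) and phosphofructokinase Pfkp (-1.91).

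Lists without a call as a set under nocodazole held large changes in both directions, with the same counts adjusted over the list alone unless given. Immediate early genes rose in 18 and fell in 10 of 32 (18 and 11 adjusted over the list alone, adjusted p = 0.262), with the AP-1 members Fosl1 (5.62 ± 0.22, 45.9 ± 6.11 against 0.932 ± 0.253 CPM) and Jun (2.11) higher and Fos (-2.42) lower. Among D-cyclin and early G1 genes (6 up, 11 down, adjusted p = 0.192, median -0.28 and mean 0.052), Ccnd1 (-0.89) and Fzr1 (-2.08) fell and Cdkn1c (2.12), the inhibitor p57, and Rb1 (1.73) rose. The stress response list (9 up, 16 down, adjusted p = 0.0918) had asparagine synthetase Asns (-2.30) and Atf4 (-1.35) lower. Heat shock genes (8 up, 10 down, adjusted p = 0.359; median -0.16, mean 0.12) had Hspa1a (2.97) higher and Hspa4 (-0.93) lower. Cholesterol synthesis (7 up, 9 down, adjusted p = 0.720) had Sqle (-1.15) lower, and primitive endoderm genes were 5 up and 8 down (adjusted p = 0.332). The largest rises were in the signalling regulator Rgs14 (5.74 ± 0.26), Fosl1, Apol8 (5.41), the adhesion gene Pvrl4 (4.78), Ltb4r1 (4.64) and the tubulin-modifying enzyme Ttll6 (4.15), and the largest falls in Zfp951 (-5.26 ± 0.20), Arl14epl (-5.12), Fkbp6 (-4.76) and the receptor gene Adgrg6 (-4.65). Of 15905 genes, 5766 rose and 4876 fell; scaling by total counts alone shifts the median of all genes by 0.16, 0.35 and 0.19 for nocodazole, thymidine and CDK1i against asynchronous cells, and the changes are relative to the main scaling. Asynchronous cells were fresh and without EdU, while treated cells were given EdU, ethanol-fixed and stained. Drug, EdU and fixation therefore differ together in all 3 comparisons with asynchronous cells.

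After double thymidine, used to stall replication, mitotic and replication genes fell together. Of 63 G2/M genes 56 fell and 5 rose (56 and 5 adjusted over the list alone; median -0.73, adjusted p = 1.08e-10 and adjusted p = 0.118 with an estimated correlation). Kif11 (-1.99 ± 0.074), the cytokinesis factors Ect2 (-1.89) and Anln (-1.64), Plk1 (-1.36), Ccnb1 (-0.96) and Cdk1 (-0.59) fell. In the G1/S list 33 fell and 7 rose (33 and 7 adjusted over the list alone; median -0.38, adjusted p = 0.000852 and adjusted p = 0.160 with an estimated correlation). Hells (-1.96), Pola1 (-1.61), Mcm2 (-1.42 ± 0.069, 315 ± 6.13 against 841 ± 44.8 CPM) and Mcm4 (-1.39) were among the falls. Ccne1 had -0.14 (adjusted p = 0.0755), which turned to 0.21 with scaling by total counts alone (adjusted p = 0.00755). p53 targets rose in 23 and fell in 6 of 34 genes (23 and 6 adjusted over the list alone; median 0.59, adjusted p = 0.0102 and adjusted p = 0.298 with an estimated correlation). Cdkn1a (0.82), Tap1 (2.95) and Perp (2.16) rose. Chaperones fell, 15 against 3 up (15 and 3 adjusted over the list alone; median -0.58, adjusted p = 0.00250 and adjusted p = 0.160 with an estimated correlation). Hspa4 (-1.69), Hsp90aa1 (-1.42) and the mitochondrial chaperonin Hspd1 (-1.27) fell. Cholesterol synthesis fell, 15 against 5 up (15 and 5 adjusted over the list alone; median -0.56, adjusted p = 0.0214 and adjusted p = 0.160 with an estimated correlation). Squalene epoxidase Sqle (-1.74) and Hmgcs1 (-1.01) were lower. The stress response list fell, 20 against 7 up (20 and 7 adjusted over the list alone; median -0.39, adjusted p = 0.0118 and adjusted p = 0.514 with an estimated correlation), with Asns (-1.95).

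Pluripotency genes fell after thymidine in 28 of 42 genes and rose in 11 (28 and 11 adjusted over the list alone; median -0.57, adjusted p = 0.00566 and adjusted p = 0.127 with an estimated correlation). Dnmt3l (-3.51), Nr0b1 (-1.44), Nanog (-0.65) and Pou5f1 (-0.51) were lower, and Id2 (1.77) higher. All 12 2-cell-like genes fell (12 adjusted over the list alone; median -3.29, adjusted p = 0.000604 and adjusted p = 0.118 with an estimated correlation), Zscan4d (-3.64) and Zscan4e at least 18.6-fold. Fibroblast markers rose in 13 of 16 (13 adjusted over the list alone; median 2.69, adjusted p = 0.00151 and adjusted p = 0.160 with an estimated correlation). Acta2 (6.21) and Col1a1 (3.56) rose. All 9 mitochondrially encoded genes rose (9 adjusted over the list alone; median 1.02, adjusted p = 0.00443 and adjusted p = 0.261 with an estimated correlation), at 4.73% and 4.40% of counts. Lineage markers were 22 up and 11 down (adjusted p = 0.0700), with Krt18 (3.70), Tfap2c (3.34) and the Nodal antagonist Lefty1 (3.38) higher. Immediate early genes were 15 up and 14 down, with a median of 0.29 and a test in the other direction (adjusted p = 0.984); Egr1 rose (1.47) and Fos fell (-1.51). The 5 other lists did not pass, with the same counts adjusted over the list alone apart from histones (1 and 2): histones 2 up and 2 down, D-cyclin genes 6 and 10, primitive endoderm 5 and 7, glycolysis 10 and 17, and ribosomal proteins 40 and 9, with adjusted p from 0.119 to 0.984. Ccnd1 (-0.68) and Myc (-0.91) fell. The largest rises were in the peptide transporter Slc15a2 (5.41 ± 0.21), Ttll6 (4.89), the axonal motor Kif1a (4.88) and annexin Anxa8 (4.56), and the largest falls in Zfp951 (-7.50 ± 0.26, 0.265 ± 0.194 against 48.5 ± 3.38 CPM), RP24-231B8.6 (-5.82), Arl14epl (-5.05) and Meis2 (-4.95). In all, 6087 genes rose and 5489 fell; with total counts alone, 8308 rose and 3714 fell, 69.1% in place of 52.6% higher.

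With CDK1 inhibited, used to stop cells before mitosis, mitotic genes fell and replication genes went both ways. Of 63 G2/M genes 55 fell and 2 rose (57 and 2 adjusted over the list alone; median -0.71, adjusted p = 4.22e-12 and adjusted p = 0.0507 with an estimated correlation). Prc1 (-2.04 ± 0.094), Kif11 (-1.89), the hyaluronan receptor Hmmr (-1.74), Plk1 (-1.24), Ccnb1 (-1.15) and Cdk1 itself (-0.92 ± 0.073, 157 ± 6.01 against 295 ± 3.54 CPM) were lower. G1/S genes rose in 26 and fell in 19 of 55 (27 and 19 adjusted over the list alone, adjusted p = 0.330), with the activator E2f1 (1.36) and Ccne1 (0.55) higher and Pola1 (-0.99) and Mcm2 (-0.40) lower. p53 targets did not pass as a set, 9 up and 14 down (adjusted p = 0.0987), and Cdkn1a had -0.085 (adjusted p = 0.337). Pluripotency genes fell in 31 of 42 and rose in 5 (32 and 5 adjusted over the list alone; median -0.57, adjusted p = 1.93e-05 and adjusted p = 0.0507 with an estimated correlation). Dnmt3l (-2.86), Tbx3 (-2.81), Klf4 (-1.87), Nanog (-0.81) and Pou5f1 (-0.55) fell and Id2 (2.77) rose. All 12 2-cell-like genes fell (12 adjusted over the list alone; median -5.28, adjusted p = 1.46e-05 and adjusted p = 0.0507 with an estimated correlation), with Zscan4d at -6.12. Fibroblast markers rose in 12 and fell in 1 of 16 (12 and 1 adjusted over the list alone; median 1.65, adjusted p = 0.0165 and adjusted p = 0.264 with an estimated correlation). Mmp2 rose (1.58), and collagen Col3a1 was at least 12.2-fold higher. Mitochondrially encoded genes rose in 7 of 9 (7 adjusted over the list alone; median 0.62, adjusted p = 0.0165 and adjusted p = 0.372 with an estimated correlation), at 3.38% and 3.32% of counts. Glycolysis and hypoxia genes fell in 18 and rose in 5 (18 and 5 adjusted over the list alone; median -0.33, adjusted p = 0.0194 and adjusted p = 0.535 with an estimated correlation), with Hk2 at -1.26.

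RP23-81C12.1, whose function is not known from its name, rose most with CDK1i (5.24 ± 0.12, 8350 ± 1251 against 221 ± 5.12 CPM). With Rn18s-rs5 and n-R5-8s1, copies of ribosomal RNA genes, it made up a share, mostly its own in the CDK1i libraries alone, of 0.898% and 1.10% of counts with CDK1i, 0.109% and 0.124% with thymidine, 0.0688% and 0.0624% with nocodazole and 0.0506% and 0.0539% in asynchronous cells. Next came the muscle actinin Actn2 (4.81), RP24-248F14.2 (4.71), Nrbp2 (4.29), Slc15a2 (4.23) and Dpysl2 (3.85). The largest falls were in Fkbp6 (-5.15), Zfp951 (-4.96), Adgrg6 (-4.57), Catip (-4.49) and Arl14epl (-4.46). Among lists that did not pass, counts adjusted over the list alone differed for p53 targets (9 up, 15 down), stress response (9, 17), cholesterol synthesis (11, 9) and ribosomal proteins (3, 9). Fos fell (-3.65) with 17 of 32 immediate early genes (6 up), and D-cyclin genes were 3 up and 12 down, with Cdkn1c (2.68) and cyclin D2, Ccnd2 (2.78), higher and Ccnd1 (-0.33) and Fzr1 (-1.75) lower. Lineage markers were 18 up and 8 down, with Tfap2c (2.55), Pax6 (2.73) and Lefty1 (2.00) higher; these 3 lists each had an adjusted p = 0.0643. Histones (2 up, 6 down), primitive endoderm (4, 8), stress response (9, 16; Asns -2.36), heat shock (8, 4; Hspa1b 2.19), cholesterol synthesis (11, 8) and ribosomal proteins (5, 11) had adjusted p from 0.106 to 0.661; the median of cholesterol synthesis was negative (-0.011) with a positive mean and test. In all, 5267 genes rose and 5077 fell; with total counts alone, 6683 rose and 3816 fell, 63.7% in place of 50.9% higher.

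Nocodazole and CDK1i cells were both fixed and stained, so their comparison leaves fixation out. p53 targets, immediate early genes and histones were higher after nocodazole, and replication genes higher after CDK1i. Of 34 p53 targets 30 were higher and 3 lower (30 and 3 adjusted over the list alone; median 1.31, adjusted p = 1.50e-13 and adjusted p = 0.0880 with an estimated correlation). Mdm2 (2.39 ± 0.078, 1084 ± 55.4 against 206 ± 1.62 CPM), Ddit4l (3.51), Tap1 (3.07), Plk2 (2.17) and Cdkn1a (1.80 ± 0.072) were higher. G1/S genes were lower in 41 of 55 and higher in 2 (41 and 2 adjusted over the list alone; median -0.44, adjusted p = 9.10e-09 and adjusted p = 0.0880 with an estimated correlation). The methylation cofactor Uhrf1 (-1.09) and the helicase subunits Mcm6 (-0.90), Mcm3 (-0.88) and Mcm4 (-0.83) were lower. Immediate early genes were higher in 23 and lower in 2 (24 and 3 adjusted over the list alone; median 0.63, adjusted p = 1.12e-06 and adjusted p = 0.0696 with an estimated correlation). Fosl1 (4.97), Jun (2.64), Egr1 (1.73) and Spry2 (1.17) were higher. Histone genes were higher in 10 of 14 (12 up and 1 down adjusted over the list alone; median 2.19, adjusted p = 0.000209 and adjusted p = 0.124 with an estimated correlation). Hist1h1c (3.54), Hist1h2bc (2.00) and H1f0 (1.88), a linker histone made outside S phase, were higher. These 14 are few of the 79 histone genes listed. G2/M genes were 29 higher and 14 lower (31 and 14 adjusted over the list alone; median 0.16, adjusted p = 0.0226 and adjusted p = 0.390 with an estimated correlation). Psrc1 (1.41), Gtse1 (1.27) and Hmmr (1.07) were higher, the phosphatase Cdc25b (-1.50) lower and Ccnb1 at 0.012 (adjusted p = 0.909).

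Ribosomal proteins were higher after nocodazole in 56 of 76 and lower in 1, Rpl13a (-0.84) (60 and 1 adjusted over the list alone; median 0.36, adjusted p = 1.12e-06 and adjusted p = 0.677 with an estimated correlation). Heat shock genes were lower in 10 and higher in 3 (10 and 3 adjusted over the list alone; median -0.18, adjusted p = 0.0450 and adjusted p = 0.390 with an estimated correlation). The cochaperone Bag3 (-1.22) and Hsph1 (-0.69) were lower. Mitochondrially encoded genes were 7 higher and 1 lower (7 and 1 adjusted over the list alone; median 0.35, adjusted p = 0.0450 and adjusted p = 0.475 with an estimated correlation). mt-Nd6 (0.90) was higher and the ribosomal RNA mt-Rnr1 (-0.57) lower. Beta tubulins were among the largest falls, Tubb5 (-2.17 ± 0.072, 488 ± 24.1 against 2199 ± 14.5 CPM) and the neuronal Tubb3 (-2.82 ± 0.10), beside RP23-81C12.1 (-4.90 ± 0.12), n-R5-8s1 (-2.88), RP24-248F14.2 (-2.29) and Megf11 (-2.12). The cartilage matrix gene Matn1 (5.54 ± 0.21), Rgs14 (5.25), Apol8 (5.14) and Ltb4r1 (4.88) were the largest rises. The 9 other lists did not pass: naive pluripotency genes were 15 higher and 14 lower (Klf5 0.92, Klf2 -0.93, Nanog -0.48, Pou5f1 0.42), lineage markers 9 and 11 (Sox1 2.26, Lefty2 -1.35), and D-cyclin genes 7 and 9 (Rb1 1.85, Ccnd1 -0.55). Stress response genes were 10 and 13 (Atf3 2.45, Ddit4 2.19), cholesterol synthesis 3 and 10, glycolysis 9 and 10, primitive endoderm 6 and 0, fibroblast markers 5 and 2 (Acta2 2.99) and 2-cell-like genes 1 and 0. Adjusted over the list alone the counts differed for naive pluripotency (15 and 16), primitive endoderm (5 and 0), stress response (10 and 15) and glycolysis (10 and 10). In all, edgeR called 4169 genes higher and 3956 lower.

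**Figure D4:**
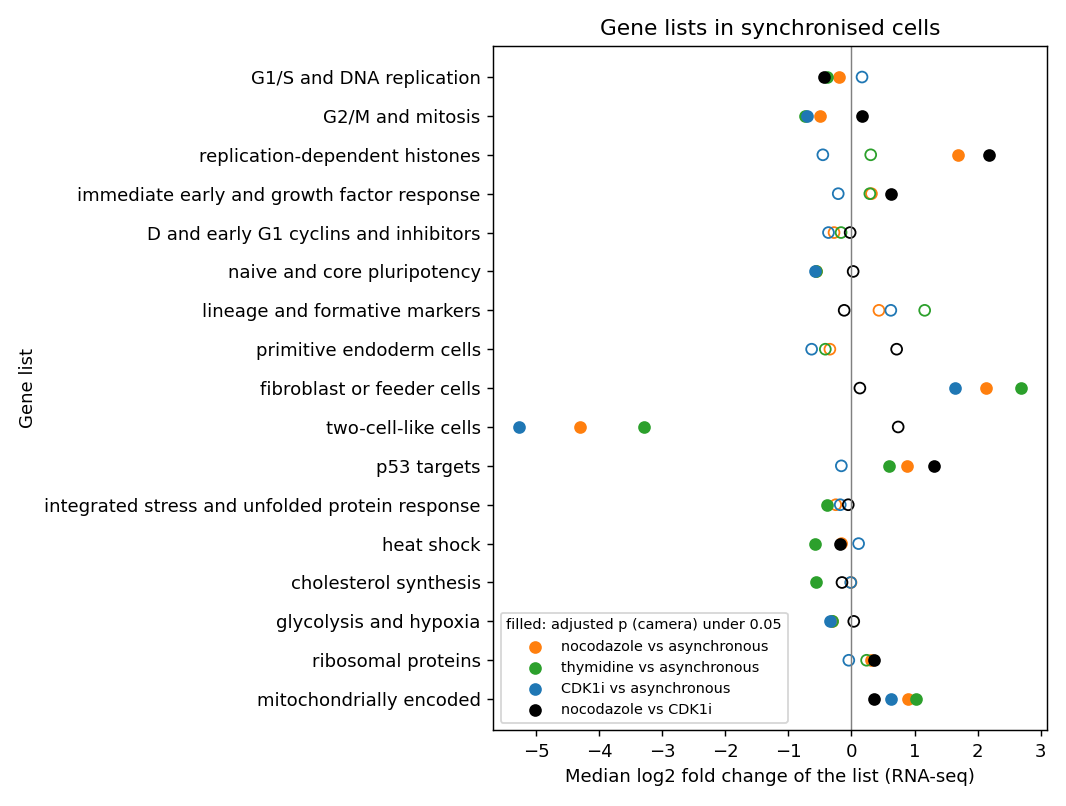
Median log2 fold change (x axis) of each fixed gene list (y axis) in the 4 RNA-seq comparisons of synchronised cells; filled circles passed camera at an adjusted p under 0.05 with the preset correlation. p53 targets have a median of 1.31 in nocodazole against CDK1i, and with an estimated correlation no list passes in any of the 4 comparisons.

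ATAC-seq of the synchronised cells, all fresh, followed the same drugs at the level of chromatin. List results here are from camera alone, as fry passed 0 of 60 in the 4 comparisons. Whether these libraries differed in enrichment over background was not tested, so changes at gene starts may hold such a difference. Promoters of p53 targets were more open after nocodazole: 28 of 32 rose and 0 fell (29 and 0 adjusted over the list alone; median 0.59, adjusted p = 5.54e-12 and adjusted p = 0.879 with an estimated correlation). The Cdkn1a promoter (chromosome 17, 29090805 to 29091072) rose by 2.27 ± 0.20 (adjusted p = 2.05e-27) and that of Ccnb1 by 0.43 ± 0.15, while the Nanog promoter (chromosome 6, 122706930 to 122707607) fell (-0.80 ± 0.16, adjusted p = 7.93e-06). Promoters of the G1/S list (19 up, 23 adjusted over the list alone, adjusted p = 0.00290), the G2/M list (19 up, 24, adjusted p = 0.0170), immediate early genes (10 up, 10, adjusted p = 0.0390) and cholesterol synthesis (7 up, 10, adjusted p = 0.0390) rose with 0 falling; with an estimated correlation the adjusted p = 0.879 for each. The largest rise with a gene was in Ehd4 (chromosome 2, 120134277 to 120134989, 3.92 ± 0.20) and the largest fall in Brinp1 (chromosome 4, 68814057 to 68814410, -3.69 ± 0.35). Of 164690 peaks, 21503 rose and 17255 fell; within 1 kb of a gene start lay 11.7% of the rises and 3.78% of the falls against 9.20% of all tested. On chromosome 9 from 3000001 to 4000000, 38 of 57 peaks fell. With total counts alone 15759 rose and 25276 fell, 38.4% in place of 55.5% higher, and DESeq2 gave 13977 and 8180, 63.1% higher. The 38758 calls became 24345 without asynchronous replicate 1, 21992 without nocodazole replicate 1 and 25366 without nocodazole replicate 2.

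After thymidine, peaks at gene starts had lower counts. The median log2 change was -0.17 within 1 kb of a gene start and 0.052 over 10 kb away, and 22.0% of the 9535 falls lay within 1 kb against 2.27% of the 19194 rises. Ribosomal protein promoters fell in 20 of 74 (28 adjusted over the list alone; median -0.28, adjusted p = 0.00219 and adjusted p = 0.989 with an estimated correlation). The promoters of Ccne1 (chromosome 7, 38106754 to 38108513, -0.56 ± 0.15) and Myc (-0.40 ± 0.15) fell, and that of Cdkn1a had 0.35 ± 0.23 (adjusted p = 0.305). A peak 5565 bp from the start of the immediate early gene Egr1 rose by 2.72 ± 0.17 (chromosome 18, 34865053 to 34865724), and a peak in Zfp600, in a zinc finger cluster, fell (chromosome 4, 146167259 to 146167701, -2.74 ± 0.39). In the surrounding Mb, 146000001 to 147000000, 42 of 77 peaks fell. DESeq2 called 9224 higher and 4164 lower, 68.9% in place of 66.8% higher. The 28729 calls became 14723 without asynchronous replicate 2, 16862 without thymidine replicate 1 and 13421 without thymidine replicate 2.

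With CDK1 inhibited, peaks at gene starts had higher counts. Of 7829 rises 39.1% lay within 1 kb of a gene start, against 3.23% of 5575 falls, with medians of 0.23 near gene starts and -0.076 over 10 kb away. Promoters rose in the lineage list (20 of 41, 27 adjusted over the list alone, median 0.44, adjusted p = 0.00838), the G1/S list (17 of 51, 34, 0.38, 0.00957), ribosomal proteins (30 of 74, 40, 0.35, 0.0151), D-cyclin genes (9 of 19, 11, 0.38, 0.0198) and the G2/M list (20 of 56, 31, 0.36, 0.0307), and likewise in immediate early genes (10 of 26, 16, 0.38, 0.0307), p53 targets (12 of 32, 15, 0.32, 0.0446) and cholesterol synthesis (11 of 25, 19, 0.41, 0.0446). Histone promoters, 1 up, 2 down and 32 not called, stayed behind other promoters (test down, adjusted p = 0.000331) with a median of -0.016, 0.017 above that of all peaks. For each list the adjusted p = 0.739 with an estimated correlation. The Cdkn1a promoter rose by 0.88 ± 0.23 (adjusted p = 0.00462). With total counts alone 4773 rose and 12725 fell, 27.3% in place of 58.4% higher, and DESeq2 gave 6404 and 1439, 81.7% higher, with the median of all peaks shifted by 0.14. The 13404 calls became 5633 without CDK1i replicate 2 and 4387 without asynchronous replicate 1.

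Between nocodazole and CDK1i, both without fixation, p53 target promoters were more open after nocodazole, 12 higher and 0 lower (14 and 1 adjusted over the list alone; median 0.32, adjusted p = 5.12e-10 and adjusted p = 0.982 with an estimated correlation). The Cdkn1a promoter was higher by 1.39 ± 0.20 (adjusted p = 1.67e-10) and that of Nanog lower (-0.55 ± 0.17, adjusted p = 0.00937). Lineage promoters were 2 higher and 14 lower (2 and 21 adjusted over the list alone; median -0.38, adjusted p = 0.000380 and adjusted p = 0.982 with an estimated correlation), and histone promoters were higher relative to other promoters (1 called, 34 not called, median 0.12, adjusted p = 0.00211 and adjusted p = 0.982 with an estimated correlation). The largest rise was in Arfgef2 (chromosome 2, 166809606 to 166809767, 4.82 ± 0.46). In all 15952 peaks were higher and 9493 lower, and 8760 and 5095 by DESeq2; the 25445 calls became 16861 without CDK1i replicate 2, 14590 without nocodazole replicate 1 and 15869 without nocodazole replicate 2. Across 12924 genes, promoter accessibility and RNA changes in this comparison had a Spearman rho of 0.204 (permutation p = 1e-05, the smallest possible, adjusted p = 1.33e-05 over 4 relations added after the data were seen); against asynchronous cells rho was 0.0659 for nocodazole, 0.0741 for thymidine (both permutation p = 1e-05, adjusted p = 1.33e-05) and -0.0303 for CDK1i (permutation p = 0.0005, adjusted p = 0.0005), and genes are not independent replicates.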

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

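Tests of early replication, of RNA scaling, of a single CDK1i library, of tubulin mRNAs and of the genes called between nocodazole and CDK1i were chosen only after the result was seen. Bootstrap intervals below describe the spread over peaks or genes, not between libraries. They do not give the precision over replicates.

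Peaks at gene starts were lower in S than in G1. A weaker enrichment of the S libraries that lowers all peaks of the same counts alike is argued against. Promoter peaks lay below distal peaks of matched CPM by a median difference of -0.50 (95% bootstrap interval -0.516 to -0.472), in 20 of 20 bins. Peaks were matched in CPM alone, not in width or GC content, so weaker enrichment at gene starts in particular is not excluded. Fewer counts in S do not account for it, since with every library thinned to 1102935 counts the promoter median was -0.30 (-0.319 to -0.278). Extra copies of early-replicating DNA would raise gene-dense regions, but the test of this decides nothing: across distal peaks the Spearman rho of gene density and change was -0.304 (-0.313 to -0.295), and as low in G2M against G1 (-0.320), where copies are even. A bias by GC content may remain, as no genome sequence was at hand to test it, and a real change of chromatin in S phase stays open beside it.

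Over 10000 genes changed in each RNA-seq comparison with asynchronous cells. EdU was given to the treated cells only, so it cannot be told apart from the drugs either. Fixation and staining of the treated cells alone cannot be told apart from the drugs: the difference in promoter accessibility between genes called higher and lower was 0.0320 for nocodazole (95% bootstrap interval 0.0194 to 0.0427), 0.0368 for thymidine (0.0240 to 0.0499) and -0.0184 for CDK1i (-0.0325 to -0.00502), but RNA can change without accessibility, so this keeps it open. For this test the bound fixed beforehand was met on the side that named fixation and staining alone as the cause. The reading as open was settled after the values were seen. Fixation does not explain the 8125 genes called between nocodazole and CDK1i, both fixed and stained. The choice between TMM factors and total counts does not account for most calls. With total counts only, 9699 of 10642 kept sign and call for nocodazole, 9801 of 11576 for thymidine and 9083 of 10344 for CDK1i. The balance of rises and falls moved with this choice (69.1% higher for thymidine). Both scale within a library, so a change of total RNA per cell could not be seen and stays open.

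RP23-81C12.1 and the ribosomal RNA genes Rn18s-rs5 and n-R5-8s1 were higher with CDK1i. A single deviating library is argued against for the summed share of the 3, a measure chosen after the values were seen: the lower CDK1i library was 7.23 times the highest other library, mostly through RP23-81C12.1 (7533 against at most 485 CPM). It is argued against for the ribosomal RNA genes too, with a bound set after the values were seen: the lower CDK1i library was 1.90 times the highest other library for Rn18s-rs5 and 2.31 times for n-R5-8s1, while libraries of the same group differed by at most 1.18 and 1.49 times. More RNA without a poly(A) tail cannot be told apart. In CDK1i against nocodazole 48 small RNA genes had a median of -0.11 (95% bootstrap interval -0.329 to 0.0652), with 3 higher and 4 lower. A bound written beforehand was met on the side against this cause. The median level of these genes, 1.17 CPM, and the short length of such RNAs leave the test without force. An effect of CDK1 inhibition on these RNAs was not tested.

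The 6 G1 and S SLAM-seq libraries can be split in 10 ways, the real one included, too few for a share under 0.05. For new RNA 3 of the 10, the real one among them, gave at least its 1 call (highest other 1), and for all reads 1 of the 10, the real one, gave its 285 (highest other 2).

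Several lists drew attention because they differed between 2 groups handled alike, nocodazole and CDK1i: the median log2 change was -0.44 for G1/S genes, 2.19 for histones, 0.63 for immediate early genes, 1.31 for p53 targets, -0.18 for heat shock genes and 0.36 for ribosomal proteins. Mitochondrial peaks, left out of the tests, drew attention by their share of peak counts in sorted ATAC-seq: 52.4% and 54.7% in G1, 62.6% and 56.4% in S and 53.3% and 50.2% in G2M.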

How the results depend on the processing

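Of the alternatives, only the mitochondrial peaks kept were chosen after the data were seen. Of 3001 list results 2761 stayed the same, 202 became weaker, 38 stronger and 0 reversed. Of 9621 results of named genes and peaks 9302 stayed, 223 became weaker, 95 stronger and 1 reversed. Results that had not passed to begin with are counted too, so these totals do not measure robustness. In sorted ATAC-seq, where camera passed 0 lists, 465 of 466 list results stayed. In new RNA, with 1 called gene, 2340 of 2355 named results stayed. Of the 251 list results, camera with the preset correlation passed 75 and fry 97, with 48 in common and 0 of them in opposite directions. With an estimated correlation in camera, 72 of these 75 no longer passed. Only the G2/M list still did, in new RNA of G2M against S (adjusted p = 0.0488) and in all SLAM-seq reads. There the adjusted p was 0.00172 in G2M against S and 0.00290 in G2M against G1. Nearly every list result thus rests on the preset correlation. Camera alone passed 18 in synchronised ATAC-seq, 6 in new RNA, 2 in RNA-seq (ribosomal proteins after nocodazole against asynchronous and against CDK1i cells) and 1 in all SLAM-seq reads (fibroblast markers in G2M against G1), and fry alone 21 in sorted ATAC-seq, 23 in RNA-seq, 4 in all SLAM-seq reads and 1 in new RNA. The reversed gene was Ccne1 in thymidine against asynchronous cells, 0.21 with total counts only; the cause was not tested. Correlations over called genes alone were not run, since new RNA had 1, 0 and 0 such genes.

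DESeq2 called 7843 peaks in CDK1i against asynchronous cells, 13855 in nocodazole against CDK1i, 22157 with nocodazole and 13388 with thymidine. In sorted ATAC-seq it called 353 in G2M against G1, 840 in G2M against S and 1355 in S against G1. In the same order it called 4, 1 and 36 genes in new RNA and 76, 73 and 542 in all SLAM-seq reads.

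With only the 2 groups compared, 8196 peaks were called for CDK1i, 2077 in S against G1 of sorted ATAC-seq and 0 genes in new RNA of S against G1. For all SLAM-seq reads 8 were called in G2M against G1, 28 in G2M against S and 167 in S against G1. With no low count filter the counts were 26, 2 and 36 in new RNA and 83, 53 and 496 in all reads, in that order. Scaling T>C reads by all reads gave 5 in S against G1. With total RNA in place of new RNA, rho was 0.0314 for promoters in G2M against S (adjusted p = 0.0164), 0.0317 for promoters in G2M against G1 (adjusted p = 0.0158) and 0.0466 for distal elements in G2M against G1 (adjusted p = 0.00084).

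With the replicate number as a replicate block, 3 genes were called in new RNA of G2M against G1, 0 in G2M against S and 1 in S against G1, and 22, 20 and 333 in all reads. RNA-seq gave 10463 calls for nocodazole, 11430 for thymidine, 10179 for CDK1i and 7780 for nocodazole against CDK1i, and synchronised ATAC-seq 41907, 31221, 15939 and 27428. Sorted ATAC-seq gave 1068 in G2M against G1, 1686 in G2M against S and 3373 in S against G1. Same-numbered replicates shared little, with a correlation of deviations of at most 0.137; the labels do not say whether equal numbers mark a pair.

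Leaving out 1 library at a time, synchronised ATAC-seq gave 4387 to 12641 calls for CDK1i, 14590 to 21172 for nocodazole against CDK1i, 21992 to 30412 for nocodazole and 13421 to 20879 for thymidine. Sorted ATAC-seq gave 294 to 934 in G2M against G1, 1115 to 1331 in G2M against S and 2177 to 3152 in S against G1. RNA-seq gave 8671 to 9205 for CDK1i, 5805 to 8195 for nocodazole against CDK1i, 9077 to 10708 for nocodazole and 10307 to 11082 for thymidine. New RNA gave 0 to 2 without 1 library in G2M against G1, 0 in G2M against S and 0 to 2 in S against G1, and all SLAM-seq reads 5 to 25, 3 to 13 and 82 to 262. The labelled share of S minus G1 ranged from 1.03 to 1.75 points, G2M minus G1 from 1.09 to 1.74 and G2M minus S from -0.248 to 0.397. Conversions per T position were 0.613% in G1, 0.788% in S and 0.737% in G2M, which put G2M below S (-0.0514 points, exact p = 0.30).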

Other observations

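The tubulin test was chosen only after the result was seen. Alpha and beta tubulin mRNAs were mostly lower after nocodazole than after CDK1i: of 13 genes 10 were lower and 3 higher, with a median of -0.96, while 4 gamma, delta and epsilon tubulin genes had a median of 0.0042, with 0 lower and 1 higher (Tube1). Tubb3 (-2.82), Tubb5 (-2.17) and Tuba1b (-1.88) were lowest, and Tuba3a (1.03), Tuba3b (2.55) and Tubb6 (0.69) higher. Cells degrade alpha and beta tubulin mRNAs when free tubulin rises, as it does when nocodazole takes microtubules apart, and the median of -0.96 is in line with such decay, as a hypothesis found and tested on the same data. The difference in medians between the 2 families was -0.97 (exact permutation p = 0.176, two-sided), so the families were not shown to differ, and tubulin copies can share reads.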
